A study of Homo sapiens with 9 samples.

How the data were processed

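RNA of CAL33 and KYSE180 cells, parental or with acquired resistance to BYL719, was measured in 9 libraries. Per the labels' protocols, poly(A) RNA was isolated from 1 µg of total RNA with a RIN above 7, fragmented with RNase III, made into libraries with the Ion Total RNA-Seq Kit v2 and 16 cycles of PCR, and sequenced on an Ion Proton. CAL33 cells were grown in DMEM-F12 and KYSE180 cells in RPMI, per the labels. Fragment reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only.

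The deposited values are whole-number read counts per Ensembl gene, not normalised. The submitters' processing notes name BWA, HTSeq and DESeq2 without versions or roles, and the hg19 build. The annotation release, the strand setting of the counting and any filter are not given in the sources used here, so genes that overlap or lie antisense to each other, and genes with near-identical copies, are uncertain. The table held 55841 genes and 5 summary lines of the counter, which stayed out of library sizes and tests. Of all reads in the table, 63.42% to 72.33% per library were assigned to genes, 8.112% to 16.88% were not aligned, 7.788% to 9.791% aligned in several places, 8.445% to 11.7% fell in no feature and 1.385% to 1.523% were ambiguous. Gene symbols were taken by Ensembl identifier from a GENCODE annotation of GRCh38, which matched 49395 identifiers holding 99.28% of the counts, and no coordinates are given because that build is not the one of the files.

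Libraries were grouped by the titles and the resistance label, and columns were matched to libraries by the description labels. Counts in genes per library were 21629958 to 44124404, with 23299 to 24941 genes detected. Replicates differed by more than sampling noise, with chi-square per degree of freedom of 11.97 to 46.37 over genes with at least 20 counts, so none was counted as a duplicate.

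Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F test). All 9 libraries entered 1 model of group means, so that the 4 groups shared an estimate of the spread (common biological coefficient of variation 0.163), and p-values were adjusted by Benjamini-Hochberg over 20154 genes with a threshold of 0.05. The 3 contrasts were resistant minus parental in CAL33, the same in KYSE180, and the difference between them. The SE of a log2 fold change was its absolute value divided by the square root of F, and CPM values were computed with TMM factors. The overlap of the 2 lists of called genes was compared with independent lists per direction by a one-sided Fisher's exact test.

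Before the data were examined, 33 gene lists were fixed, including markers of fibroblasts, endothelium, blood and neural or melanocytic cells. Each list was tested two-sided with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 66 list results, and separately over 33 for the difference. An estimated correlation and fry were alternatives. Changed members were counted by p-values adjusted over all genes and adjusted over the list alone.

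Genes to be named were fixed by rule before the data were examined. The rule took the 8 largest rises and 8 largest falls per line among called genes with at least 5 CPM in the higher group and no overlap of libraries, 5 genes whatever their values, up to 3 members of each list called by camera or with at least 4 changed members (1 CPM or more), the 8 largest shared rises and falls, and the 5 largest differences in each direction. It gave 171 genes. After their values were known, the number was reduced by keeping only the largest member of lists that were not called. Of those left, 3 genes are not reported here and 121 are named, while the tests and counts of lists include all members. A gene at 0 in a group was given a bound from a floor of 3 counts over the group, or no fold where both groups were at or under it. Such a bound leaves out the counting error of the other group. Ratios over 1 to 3 counts have exact 95% intervals.

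The fitting procedure was tested on simulated counts with known fold changes. Changed genes were drawn only from well-counted genes, and the spread followed the fitted trend with level, with no library set apart. The shares recovered therefore do not describe low-count genes or libraries that deviate as some of these do. In simulated CAL33 data (19666 genes), 26.9%, 73.1% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 3 false calls among 136. In simulated KYSE180 data (19656 genes) the shares were 25.4%, 76.1% and 100%, with 7 false calls among 141.

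Alternatives were DESeq2 size factors, upper-quartile factors, no filter, CPM of at least 1 in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, each line fitted alone, a 2-fold minimum, an adjusted p under 0.01, the replicate number of the title or of the description as a block, and leaving out each library in turn. A further one, chosen after the data were seen, removed per library the trend of counts with GC content and length of the transcripts in the GRCh38 annotation, which covered 97.2% of tested genes. The patterns weighed in the closing part, and most tests applied to them, were also chosen after results were seen, and some replaced earlier tests whose values are given there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.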

Results

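Poly(A) RNA was sequenced from 2 squamous carcinoma cell lines, CAL33 from a head and neck tumour and KYSE180 from an esophageal tumour. Each line was present as parental cells and as a derivative with acquired resistance to BYL719 (alpelisib), an inhibitor of the alpha isoform of the PI3K catalytic subunit. The 9 libraries comprised 2 of CAL33 parental, 3 of CAL33 resistant, 2 of KYSE180 parental and 2 of KYSE180 resistant cells. Counts assigned to genes ranged from 21629958 (KYSE180 resistant replicate 2) to 44124404 (CAL33 parental replicate 1), and 20154 genes passed the filter on low counts. The labels mention a 24 h exposure to 1 µM BYL719 or to DMSO without saying which library received which. Each comparison is therefore between resistant and parental libraries whatever their exposure. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. KYSE180 resistant replicate 2 stood apart from the other libraries, with 16.88% of its reads unaligned (8.11% to 10.9% in the others) and 63.42% assigned to genes (68.76% to 72.33% in the others). Mitochondrial genes took 4.168% of its gene counts (6.209% to 7.713% in the others). All log2 fold changes are resistant minus parental and are given ± SE, and levels are group means of normalised counts scaled per library (CPM).

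The study's title names the receptor tyrosine kinase AXL, EGFR, PKC and mTOR. AXL (ENSG00000167601) was therefore examined first, with its ligand GAS6 (ENSG00000183087), EGFR (ENSG00000146648), the drug's target PIK3CA (ENSG00000121879) and the kinase PRKCA (ENSG00000154229). AXL rose in both lines. In CAL33 it went from 3.54 ± 0.291 CPM (SD, n = 2) to 27.6 ± 2.18 CPM (SD, n = 3), a log2 fold change of 2.96 ± 0.17. In KYSE180 it went from 15.8 ± 1.33 to 88.7 ± 2.59 CPM (SD, n = 2 each), a log2 fold change of 2.49 ± 0.16. The edgeR quasi-likelihood adjusted p was 2.56e-08 in CAL33 and 8.54e-08 in KYSE180. The difference between the rises did not pass the test (0.47 ± 0.22, adjusted p = 0.185). AXL was picked by the study on these cells, so its direction here is not independent evidence. GAS6 rose in KYSE180 from 27.2 to 53.3 CPM (0.97 ± 0.20, adjusted p = 0.00226), and the adjusted p was 0.0501 without KYSE180 parental replicate 1. In CAL33 the value for GAS6 was 0.25 ± 0.18 (adjusted p = 0.424), and the difference between the lines did not pass the test (adjusted p = 0.0835). EGFR fell in KYSE180 from 1290.0 to 546 CPM (-1.24 ± 0.13, adjusted p = 1.11e-05). In CAL33 it was at 807 CPM in parental and 773 CPM in resistant libraries (-0.06 ± 0.12, adjusted p = 0.823), and this difference between lines passed the test (adjusted p = 0.00048). PRKCA, which encodes protein kinase C alpha, rose in CAL33 (0.83 ± 0.17, adjusted p = 0.00411), and the adjusted p was 0.0539 without CAL33 parental replicate 1. It also rose in KYSE180 (0.64 ± 0.19, adjusted p = 0.0201), and the adjusted p was 0.127 without KYSE180 parental replicate 1, 0.104 without KYSE180 parental replicate 2 and 0.0717 without KYSE180 resistant replicate 1. PIK3CA passed the threshold in neither line. Its value was -0.39 ± 0.17 in CAL33 (adjusted p = 0.166, and 0.0424 without KYSE180 resistant replicate 2). In KYSE180 PIK3CA was at -0.24 ± 0.19 (adjusted p = 0.393, and 0.0332 without KYSE180 resistant replicate 1).

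**Figure D1:**
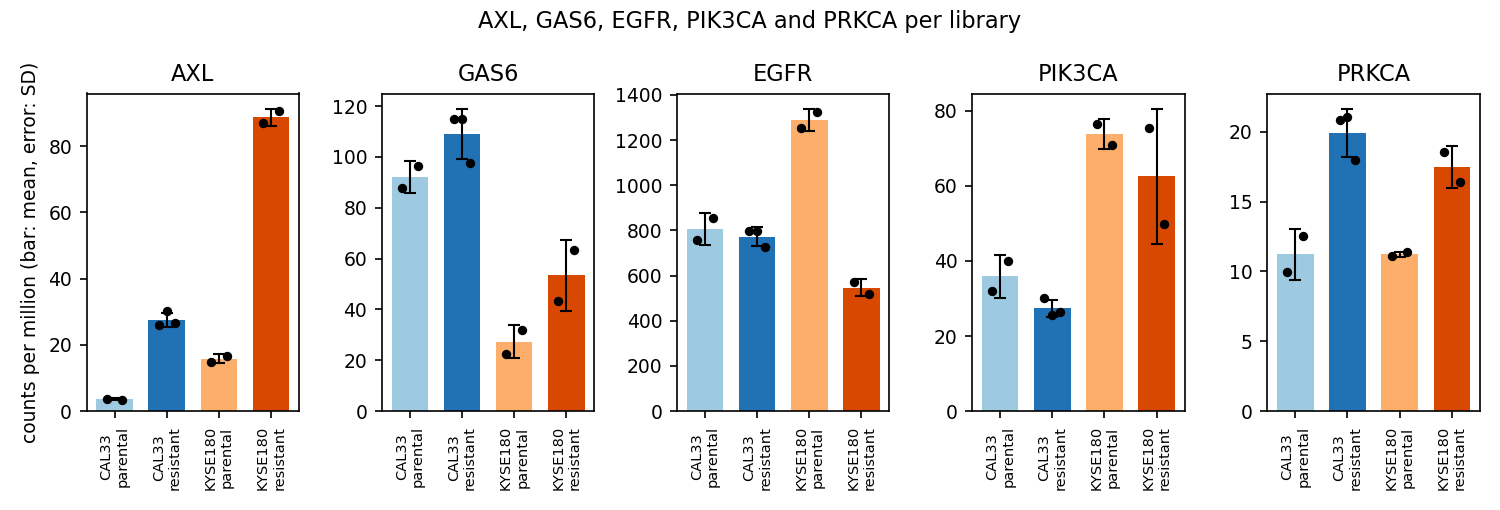
Levels in CPM of AXL, GAS6, EGFR, PIK3CA and PRKCA in each library, with bars at the group mean, error bars of 1 SD and points for libraries (n = 2, 3, 2 and 2). AXL was at 3.33 and 3.74 CPM in CAL33 parental and at 26.1 to 30.1 CPM in CAL33 resistant libraries, and at 14.9 and 16.8 against 86.9 and 90.6 CPM in KYSE180.

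The CAL33 comparison asked which transcripts differed between resistant cells and their parent. In resistant CAL33 cells the transcripts of ceruloplasmin, of the polymeric immunoglobulin receptor and of an MHC class II gene fell, and those of lumican and N-cadherin rose. CP, encoding the copper-carrying ferroxidase ceruloplasmin, fell from 216 to 1.58 CPM (-7.08 ± 0.32), and its pseudogene CPP fell by a similar measure (-7.09 ± 0.42). The cytochrome P450 genes CYP4Z1 (-5.85 ± 0.44) and CYP4X1 (-5.01 ± 0.30) and the polymeric immunoglobulin receptor PIGR (-5.08 ± 0.34) were also among the 8 largest falls. The others were the MHC class II gene HLA-DRB1 (-4.90 ± 0.49), VNN2 (-4.72 ± 0.46) and PLXDC2 (-4.53 ± 0.21). LUM, the matrix proteoglycan lumican, rose from 0.0847 to 9.17 CPM (6.58 ± 0.47), and CDH2, which is N-cadherin, from 1.16 to 25.4 CPM (4.44 ± 0.23). The other 6 of the largest rises were those of the nuclear factor TOX (5.51 ± 0.33), FGF13 (4.35 ± 0.41), EYA1 (4.12 ± 0.41), TENM2 (4.03 ± 0.19), the ephrin receptor EPHA3 (3.68 ± 0.39) and NPR3 (3.67 ± 0.22). All 16 had edgeR adjusted p of at most 1.36e-05. Reads of CP and CPP cannot be separated with certainty, and CYP4Z1 and HLA-DRB1 also have near-identical relatives. In all, 2709 genes changed, 1082 higher and 1627 lower in resistant cells, of which 368 and 762 changed at least 2-fold. With CAL33 fitted alone 1665 were higher and 1751 lower. The count was 1534 without CAL33 parental replicate 2, 1649 without CAL33 resistant replicate 2, and 4666 with the GC and length trend removed per library, a setting chosen after the data were seen.

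Sterol and lipid synthesis genes had 0 higher and 15 lower of 19 tested members (0 and 16 adjusted over the list alone), with a median of -0.74. For sterol and lipid synthesis genes the camera adjusted p was 3.07e-09, and adjusted p = 0.243 with an estimated correlation. Without CAL33 parental replicate 2, 9 members of the sterol list passed as lower. SCD, the stearoyl-CoA desaturase, fell from 176 to 13.5 CPM (-3.70 ± 0.16). HMGCS1, the cytosolic HMG-CoA synthase, fell from 135 to 43.3 CPM (-1.64 ± 0.17). Targets of the YAP and TEAD regulators had 10 higher and 0 lower of 15 tested members (11 and 0 adjusted over the list alone), with a median of 0.84. For targets of the YAP and TEAD regulators the camera adjusted p was 5.17e-10, and adjusted p = 0.243 with an estimated correlation. Among those that rose were AXL, ANKRD1 (2.77 ± 0.49) and DLC1 (2.65 ± 0.41). AXL is the gene the study's title is about, so its part in this count is not independent evidence. Basal squamous genes had 11 higher and 3 lower of 21 tested members (11 and 4 adjusted over the list alone), with a median of 0.45. For basal squamous genes the camera adjusted p was 0.00331, and adjusted p = 0.506 with an estimated correlation. The basal keratin KRT14, whose reads are partly shared with pseudogenes, rose from 625 to 2828 CPM (2.18 ± 0.18). The neurotrophin receptor NGFR, also on that list, fell (-1.47 ± 0.21). Epithelial junction and identity genes had 2 higher and 7 lower of 21 tested members (2 and 9 adjusted over the list alone), with a median of -0.20. For epithelial junction and identity genes the camera adjusted p was 0.0417, and adjusted p = 0.511 with an estimated correlation. The tight junction gene TJP3 (-4.02 ± 0.20) and GRHL1 (-1.19 ± 0.14) fell, and the simple-epithelium keratin KRT8 rose (1.15 ± 0.16). The epithelial list lost its call with adjusted p of 0.062 without CAL33 parental replicate 1, 0.0523 without CAL33 resistant replicate 1, 0.123 without CAL33 resistant replicate 3, 0.0507 without KYSE180 parental replicate 2, 0.0573 without KYSE180 resistant replicate 1 and 0.0503 without KYSE180 resistant replicate 2. It was also lost with a filter of 1 CPM in 2 libraries (adjusted p = 0.0529).

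Cytokines and chemokines driven by NF-kappaB had 1 higher and 11 lower of 21 tested members (1 and 12 adjusted over the list alone), with a median of -1.06. For cytokines and chemokines driven by NF-kappaB the camera adjusted p was 5.76e-05, and adjusted p = 0.243 with an estimated correlation. The chemokine genes CCL2 (-3.07 ± 0.29) and CCL20 (-2.65 ± 0.21) fell, and CXCL1 fell from 229 to 43.2 CPM (-2.40 ± 0.16). With 1 member that was at 0 in a group placed at its bound, the median of that list was -0.99. Interferon-response genes had 2 higher and 13 lower of 25 tested members (3 and 17 adjusted over the list alone), with a median of -0.66 (-0.39 without CAL33 parental replicate 2). For interferon-response genes the camera adjusted p was 8.15e-05, and adjusted p = 0.511 with an estimated correlation. The largest falls on that list were those of IFI27 (-2.99 ± 0.24), MX2 (-2.87 ± 0.21) and OAS2 (-1.83 ± 0.16), and 8 members were called lower without CAL33 parental replicate 2. Antigen presentation genes had 0 higher and 7 lower of 18 tested members (0 and 8 adjusted over the list alone), with a median of -0.28. For antigen presentation genes the camera adjusted p was 0.000463, and adjusted p = 0.506 with an estimated correlation. The members that fell most belong to the class II pathway, HLA-DRB1, the invariant chain gene CD74 (from 48.2 to 3.58 CPM, -3.75 ± 0.26) and HLA-DPA1. HLA-DPA1 fell (-3.74 ± 0.71, adjusted p = 0.00231), and the adjusted p was 0.0735 without CAL33 parental replicate 2. Genes that FOXO factors activate when PI3K signalling is low had 2 higher and 8 lower of 16 tested members (4 and 8 adjusted over the list alone), with a median of -0.48. For genes that FOXO factors activate when PI3K signalling is low the camera adjusted p was 0.0417, and adjusted p = 0.589 with an estimated correlation. Falls among them included CCNG2 (-1.94 ± 0.26) and the death ligand gene TNFSF10 (-1.73 ± 0.14). PIK3IP1, encoding a PI3K-interacting protein, fell (-1.76 ± 0.39, adjusted p = 0.00653), and the adjusted p was 0.0534 without CAL33 parental replicate 2. The FOXO list lost its call with adjusted p of 0.107 without CAL33 parental replicate 2, 0.0769 without CAL33 resistant replicate 3, 0.0507 without KYSE180 parental replicate 2, 0.0815 without KYSE180 resistant replicate 1 and 0.0687 without KYSE180 resistant replicate 2. It was also lost with a filter of 1 CPM in 2 libraries (adjusted p = 0.0526) and with the GC and length trend removed (adjusted p = 0.0847). NRF2 targets and drug-metabolism genes had 2 higher and 9 lower of 23 tested members (4 and 10 adjusted over the list alone), with a median of -0.22. For NRF2 targets and drug-metabolism genes the camera adjusted p was 0.0389, and adjusted p = 0.353 with an estimated correlation. Falls included the aldehyde dehydrogenase ALDH1A1 (-3.07 ± 0.23) and the aldo-keto reductases AKR1C3 (-2.75 ± 0.14) and AKR1B10 (-2.04 ± 0.16). The NRF2 list lost its call with adjusted p of 0.0507 without KYSE180 parental replicate 2, 0.0682 without KYSE180 resistant replicate 1 and 0.0627 without KYSE180 resistant replicate 2. It was also lost with the GC and length trend removed (adjusted p = 0.0932).

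None of the other lists passed the camera test in CAL33, although single members changed. AXL, its relatives and their ligands had 1 higher and 0 lower of 5 (1 and 0 adjusted over the list alone, camera adjusted p = 0.313). ERBB receptors and ligands had 3 higher and 2 lower of 11 (3 and 3 adjusted over the list alone, camera adjusted p = 0.921). Other receptor tyrosine kinases had 4 higher and 4 lower of 16 (6 and 5 adjusted over the list alone, camera adjusted p = 0.362). PKC and PLC enzymes had 2 higher and 2 lower of 14 (2 and 3 adjusted over the list alone, camera adjusted p = 0.79). Components of the PI3K, AKT and mTOR pathway had 1 higher and 2 lower of 22 (1 and 3 adjusted over the list alone, camera adjusted p = 0.595). MAPK output genes had 3 higher and 1 lower of 16 (5 and 3 adjusted over the list alone, camera adjusted p = 0.496). The AP-1 family had 2 higher and 0 lower of 11 (2 and 0 adjusted over the list alone, camera adjusted p = 0.395). KIT, the stem cell factor receptor, rose from 0.0875 to 2.52 CPM (4.89 ± 0.59), EPHA4 rose (2.26 ± 0.21) and the phospholipase PLCB1 fell (-2.29 ± 0.26). The ligand EGF fell (-2.09 ± 0.57, adjusted p = 0.022), and the adjusted p was 0.192 without CAL33 parental replicate 2, 0.0543 without CAL33 resistant replicate 1 and 0.0782 without CAL33 resistant replicate 3. Mesenchymal genes had 8 higher and 5 lower of 24 (11 and 5 adjusted over the list alone, camera adjusted p = 0.103). Squamous differentiation genes had 3 higher and 7 lower of 25 (4 and 8 adjusted over the list alone, camera adjusted p = 0.533). Matrix proteases and inhibitors had 3 higher and 3 lower of 17 (3 and 4 adjusted over the list alone, camera adjusted p = 0.809). TGF-beta, BMP and WNT ligands and targets had 5 higher and 3 lower of 23 (5 and 6 adjusted over the list alone, camera adjusted p = 0.636). The protease ADAMTS1 rose from 8.01 to 82.7 CPM (3.37 ± 0.17) and BMP4 from 3.6 to 28.7 CPM (2.99 ± 0.22), and the serpin SERPINB4, which has a near-identical neighbour, fell (-2.61 ± 0.23). ATF4 response genes had 2 higher and 4 lower of 17 (2 and 4 adjusted over the list alone, camera adjusted p = 0.819). Targets of p53 had 1 higher and 4 lower of 15 (1 and 7 adjusted over the list alone, camera adjusted p = 0.269). Hypoxia and glycolysis genes had 3 higher and 3 lower of 22 (4 and 4 adjusted over the list alone, camera adjusted p = 0.717). ABC transporters had 0 higher and 4 lower of 10 (0 and 4 adjusted over the list alone, camera adjusted p = 0.133). Heat shock and ER stress genes had 0 higher and 0 lower of 16 (0 and 0 adjusted over the list alone, camera adjusted p = 0.595). The serine synthesis enzyme PSAT1 (-1.24 ± 0.13) and the cholesterol exporter ABCA1 (-2.56 ± 0.29) fell. The hypoxia marker CA9 fell (-1.48 ± 0.30, adjusted p = 0.00348), and the adjusted p was 0.0546 without CAL33 parental replicate 2. GDF15, a target of p53, fell (-1.38 ± 0.33, adjusted p = 0.0107), and the adjusted p was 0.311 without CAL33 parental replicate 1. Proliferation genes had 1 higher and 5 lower of 26 (1 and 5 adjusted over the list alone, camera adjusted p = 0.299). Replication-dependent histones had 1 higher and 0 lower of 10 (1 and 0 adjusted over the list alone, camera adjusted p = 0.164). Ribosomal proteins had 0 higher and 0 lower of 24 (0 and 0 adjusted over the list alone, camera adjusted p = 0.139). Mitochondrially encoded genes had 1 higher and 0 lower of 13 (0 and 0 adjusted over the list alone, camera adjusted p = 0.299). The mitochondrial member called was MT-ND6 (0.63 ± 0.19, adjusted p = 0.0347), and the adjusted p was 0.069 without CAL33 parental replicate 1, 0.179 without CAL33 parental replicate 2, 0.0745 without CAL33 resistant replicate 1 and 0.16 without CAL33 resistant replicate 2. The mitotic gene CDC20 rose (1.06 ± 0.14). The median, the mean and the direction of the camera or fry test differed in sign for the lists of AXL relatives, ERBB ligands, other receptor tyrosine kinases, PKC and PLC enzymes and the ATF4 response. They also differed for squamous differentiation, matrix proteases, endothelial and blood cell markers, and heat shock genes. The median of -0.15 of the ABC transporter list includes the fitted value of ABCC6. That gene had no count in either CAL33 group, so it has no fold. Without CAL33 parental replicate 1 the ribosomal list (adjusted p = 0.0222) and the ABC transporter list (adjusted p = 0.0495) passed.

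The same question in KYSE180 gave falls of interferon-induced genes, mesothelin and an epithelial ETS factor, and rises of another ETS factor, transglutaminase 2 and osteopontin. XAF1, an interferon-induced gene, was at 12.6 CPM in parental libraries and had 2 counts in the resistant ones, lower by a ratio of 356, counting interval 98.2 to 2940. Mesothelin, MSLN, had 3 counts in the resistant libraries, lower by a ratio of 115, counting interval 39.1 to 560. The neuronal nitric oxide synthase NOS1 fell from 51 to 0.421 CPM (-6.94 ± 0.30) and the epithelial ETS factor EHF from 161 to 4.43 CPM (-5.18 ± 0.20). The other 4 of the largest falls were those of the neuropeptide gene NTS (-8.25 ± 0.47), CPA6 (-5.85 ± 0.39), OAS2 (-5.58 ± 0.25) and CIDEB, which overlaps a neighbouring gene (-5.22 ± 0.34). SMOC2 had 3 counts in the parental libraries and was higher in resistant ones by a ratio of 226, counting interval 76.8 to 1100. TGM2, encoding transglutaminase 2, rose from 2.45 to 107 CPM (5.45 ± 0.25), SPP1, encoding osteopontin, from 2.44 to 87.5 CPM (5.17 ± 0.27) and ANXA10 from 7.88 to 130.1 CPM (4.05 ± 0.21). The other largest rises were those of the ETS factor ETV1 (5.78 ± 0.71), the noncoding LINC01010 (5.74 ± 0.38), PRDM13 (4.83 ± 0.57) and the protease TMPRSS11D (4.20 ± 0.41). All 16 had edgeR adjusted p of at most 8.43e-05. In all, 5081 genes changed, 2576 higher and 2505 lower, of which 1144 and 1173 changed at least 2-fold. With DESeq2 size factors 2412 were higher and 2683 lower, and more were lower than higher also with upper-quartile factors (2585 and 2651), no filter (2639 and 3086), the DESeq2 Wald test (2409 and 2738) and the line fitted alone (2365 and 2403). The count was 2677 without KYSE180 parental replicate 1 and 2818 without KYSE180 parental replicate 2. Without KYSE180 resistant replicate 2 the fit called 3658 genes in KYSE180 and 3714 in CAL33.

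Interferon-response genes had 0 higher and 24 lower of 25 tested members (0 and 24 adjusted over the list alone), with a median of -2.34. For interferon-response genes the camera adjusted p was 5.94e-18, and adjusted p = 0.243 with an estimated correlation. OAS2 went from 32.8 to 0.701 CPM, BST2 from 126 to 5.03 CPM (-4.68 ± 0.25) and IFI44L from 3.29 to 0.0896 CPM (-4.92 ± 0.59). The remaining member, IRF7, had no count in resistant libraries and a mean of 0.0253 CPM in parental ones. Both groups were under the floor of 3 counts, so IRF7 has no fold, and the list median includes its fitted value. Antigen presentation genes had 0 higher and 10 lower of 18 tested members (0 and 10 adjusted over the list alone), with a median of -0.98. For antigen presentation genes the camera adjusted p was 9.73e-05, and adjusted p = 0.506 with an estimated correlation. The immunoproteasome subunits PSMB9 (-2.01 ± 0.18) and PSMB8 (-1.44 ± 0.16) fell, and the class I gene HLA-B fell from 276 to 85.8 CPM (-1.69 ± 0.16). With 2 members that were at 0 in a group placed at their bounds, the median of that list was -0.86. MAPK output genes had 10 higher and 1 lower of 16 tested members (10 and 2 adjusted over the list alone), with a median of 0.85. For MAPK output genes the camera adjusted p was 0.000134, and adjusted p = 0.243 with an estimated correlation. ETV5 rose from 6.75 to 45.4 CPM (2.74 ± 0.25), ETV4 from 24.2 to 123 CPM (2.35 ± 0.17), and the feedback inhibitor SPRY4 rose (2.65 ± 0.32). AP-1 family genes had 6 higher and 1 lower of 11 tested members (6 and 1 adjusted over the list alone), with a median of 0.67. For AP-1 family genes the camera adjusted p was 0.0221, and adjusted p = 0.506 with an estimated correlation. Rises included FOSL1 (2.63 ± 0.16) and FOS (1.81 ± 0.28). BATF3 rose (1.54 ± 0.35, adjusted p = 0.00508), and the adjusted p was 0.0709 without KYSE180 resistant replicate 2. The AP-1 list lost its call with adjusted p of 0.108 without KYSE180 parental replicate 2, 0.0786 without KYSE180 resistant replicate 1 and 0.06 without KYSE180 resistant replicate 2. It was also lost with the GC and length trend removed (adjusted p = 0.102). Receptors of the AXL family and their ligands had 3 higher and 0 lower of 5 tested members (3 and 0 adjusted over the list alone), with a median of 0.70. For receptors of the AXL family and their ligands the camera adjusted p was 0.0481, and adjusted p = 0.506 with an estimated correlation. The 3 that rose were AXL, GAS6 and TYRO3. TYRO3 rose (0.70 ± 0.16, adjusted p = 0.00463), and the adjusted p was 0.0509 without KYSE180 parental replicate 1. The study's choice of AXL put this list among those tested, so its count is not independent evidence. The call for this list was lost whichever of the 9 libraries was left out, with adjusted p from 0.0507 to 0.0694. It was also lost with DESeq2 size factors (adjusted p = 0.0502) and with a filter of 1 CPM in 2 libraries (adjusted p = 0.0529).

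Hypoxia and glycolysis genes had 2 higher and 8 lower of 22 tested members (3 and 9 adjusted over the list alone), with a median of -0.31. For hypoxia and glycolysis genes the camera adjusted p was 0.026, and adjusted p = 0.511 with an estimated correlation. Carbonic anhydrase CA9 (-4.76 ± 0.52) and EGLN3 (-1.85 ± 0.21) fell. The glucose transporter SLC2A3 rose (1.60 ± 0.46, adjusted p = 0.022), and the adjusted p was 0.171 without KYSE180 parental replicate 2, 0.0556 without KYSE180 resistant replicate 1 and 0.13 without KYSE180 resistant replicate 2. The hypoxia list lost its call with adjusted p of 0.174 without KYSE180 resistant replicate 1. Mitochondrially encoded genes had 0 higher and 4 lower of 13 tested members (0 and 8 adjusted over the list alone), with a median of -0.46. For mitochondrially encoded genes the camera adjusted p was 0.0194, and adjusted p = 0.725 with an estimated correlation. MT-ND4L fell (-0.88 ± 0.18). MT-ND6 fell (-0.63 ± 0.20, adjusted p = 0.0335), and the adjusted p was 0.299 without KYSE180 parental replicate 1 and 0.17 without KYSE180 resistant replicate 2. MT-ATP8 fell (-0.61 ± 0.21, adjusted p = 0.041), and the adjusted p was 0.117 without KYSE180 parental replicate 1, 0.147 without KYSE180 parental replicate 2 and 0.266 without KYSE180 resistant replicate 2. Mitochondrial transcripts made up 4.168% of gene counts in KYSE180 resistant replicate 2 and 6.428% in replicate 1, and without replicate 2 the adjusted p of the list was 0.202.

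**Figure D2:**
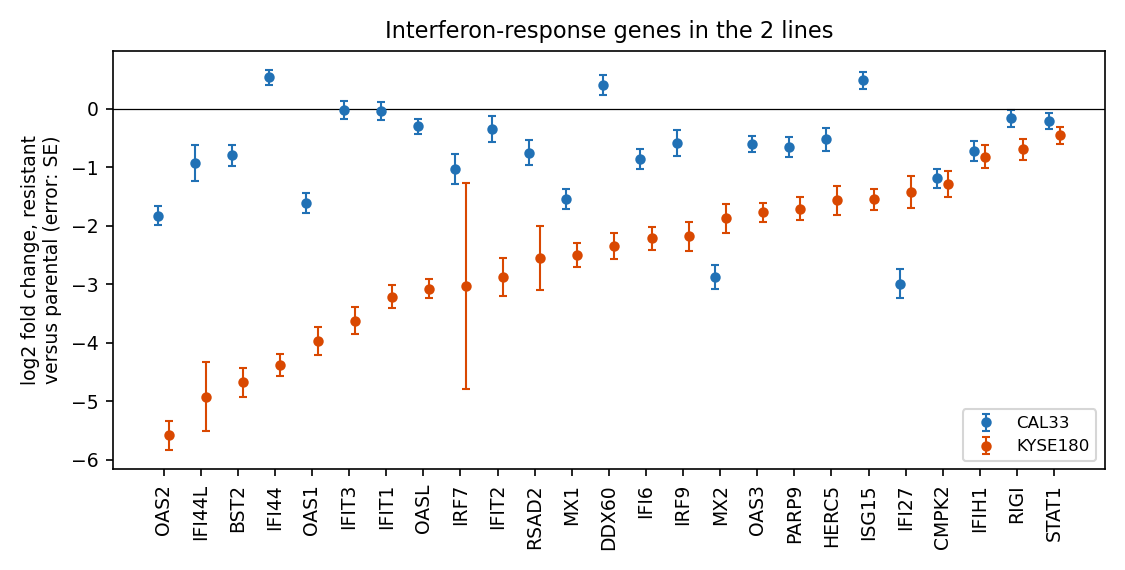
Log2 fold change (resistant versus parental, ± SE) of each of the 25 interferon-response genes in CAL33 (blue) and KYSE180 (orange), ordered by the KYSE180 value. In KYSE180, 24 of 25 fell, and in CAL33 13 fell and 2 rose, while IRF7 in KYSE180 was at 0 in the resistant libraries, so its fitted value depends on the prior count.

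The remaining lists did not pass the camera test in KYSE180. ERBB receptors and ligands had 2 higher and 5 lower of 11 (2 and 5 adjusted over the list alone, camera adjusted p = 0.198). Other receptor tyrosine kinases had 2 higher and 7 lower of 16 (3 and 8 adjusted over the list alone, camera adjusted p = 0.299). PKC and PLC enzymes had 3 higher and 3 lower of 14 (3 and 3 adjusted over the list alone, camera adjusted p = 0.673). Components of the PI3K, AKT and mTOR pathway had 4 higher and 3 lower of 22 (4 and 3 adjusted over the list alone, camera adjusted p = 0.921). FOXO targets had 3 higher and 8 lower of 16 (3 and 8 adjusted over the list alone, camera adjusted p = 0.127). YAP and TEAD targets had 6 higher and 3 lower of 15 (6 and 4 adjusted over the list alone, camera adjusted p = 0.178). The ERBB ligand BTC fell (-2.69 ± 0.34), the receptor ROR1 rose (2.27 ± 0.28) and the regulatory subunit PIK3R3 fell (-1.61 ± 0.19). FBXO32, a ubiquitin ligase gene that FOXO factors activate, fell from 12.5 to 1.07 CPM (-3.56 ± 0.20). The kinase gene PRKCQ rose (1.55 ± 0.41, adjusted p = 0.0123), and the adjusted p was 0.125 without KYSE180 parental replicate 2 and 0.0594 without KYSE180 resistant replicate 2. Epithelial junction genes had 5 higher and 2 lower of 21 (7 and 4 adjusted over the list alone, camera adjusted p = 0.38). Mesenchymal genes had 3 higher and 6 lower of 24 (3 and 7 adjusted over the list alone, camera adjusted p = 0.299). Basal squamous genes had 5 higher and 3 lower of 21 (5 and 4 adjusted over the list alone, camera adjusted p = 0.595). Squamous differentiation genes had 7 higher and 4 lower of 25 (8 and 4 adjusted over the list alone, camera adjusted p = 0.299). CLDN1, a tight junction claudin, fell (-2.23 ± 0.19), and the keratin KRT4 of stratified mucosa fell from 193 to 7.12 CPM (-4.77 ± 0.20). The mesenchymal factor PRRX1 fell (-2.59 ± 0.70, adjusted p = 0.0144), and the adjusted p was 0.103 without KYSE180 parental replicate 2, 0.0702 without KYSE180 resistant replicate 1 and 0.0733 without KYSE180 resistant replicate 2. Cytokines and chemokines had 3 higher and 9 lower of 21 (5 and 10 adjusted over the list alone, camera adjusted p = 0.0624). Matrix proteases and inhibitors had 5 higher and 6 lower of 17 (5 and 6 adjusted over the list alone, camera adjusted p = 0.8). TGF-beta, BMP and WNT ligands and targets had 5 higher and 8 lower of 23 (8 and 10 adjusted over the list alone, camera adjusted p = 0.436). The protease MMP10 fell (-2.31 ± 0.32) and TGFB2 rose (1.66 ± 0.21). ATF4 response genes had 5 higher and 2 lower of 17 (7 and 4 adjusted over the list alone, camera adjusted p = 0.299). Sterol and lipid synthesis genes had 1 higher and 8 lower of 19 (4 and 8 adjusted over the list alone, camera adjusted p = 0.447). NRF2 targets and drug-metabolism genes had 11 higher and 4 lower of 23 (12 and 7 adjusted over the list alone, camera adjusted p = 0.193). ABC transporters had 3 higher and 4 lower of 10 (3 and 5 adjusted over the list alone, camera adjusted p = 0.436). The amino acid transporter SLC7A5 rose from 744 to 2191 CPM (1.56 ± 0.16), the fatty acid synthase FASN rose (1.21 ± 0.20) and the NRF2 target OSGIN1 rose (1.91 ± 0.20). The transporter ABCC6 fell (-2.67 ± 0.81, adjusted p = 0.0305), and the adjusted p was 0.29 without KYSE180 parental replicate 1, 0.0547 without KYSE180 parental replicate 2, 0.132 without KYSE180 resistant replicate 1 and 0.135 without KYSE180 resistant replicate 2. Proliferation genes had 3 higher and 6 lower of 26 (3 and 6 adjusted over the list alone, camera adjusted p = 0.878). Targets of p53 had 2 higher and 2 lower of 15 (3 and 2 adjusted over the list alone, camera adjusted p = 0.981). Replication-dependent histones had 1 higher and 0 lower of 10 (1 and 0 adjusted over the list alone, camera adjusted p = 0.849). Ribosomal proteins had 6 higher and 1 lower of 24 (8 and 1 adjusted over the list alone, camera adjusted p = 0.117). Heat shock and ER stress genes had 6 higher and 2 lower of 16 (8 and 2 adjusted over the list alone, camera adjusted p = 0.269). Single members with a change were TYMS (-0.80 ± 0.13), FAS (-2.07 ± 0.22) and SDF2L1 (2.22 ± 0.27). RPL35, which has many pseudogenes, rose (1.01 ± 0.32, adjusted p = 0.0324), and the adjusted p was 0.0506 without CAL33 resistant replicate 2, 0.207 without KYSE180 parental replicate 2 and 0.265 without KYSE180 resistant replicate 2. The lists of PI3K pathway components, proliferation genes, p53 targets, fibroblast markers and histones had medians, means and tests that differed in sign. The ribosomal list passed without KYSE180 parental replicate 1 (adjusted p = 0.0457). The number of sterol genes called lower was 5, 1 and 5 without KYSE180 parental replicate 1, KYSE180 parental replicate 2 and KYSE180 resistant replicate 2.

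**Figure D3:**
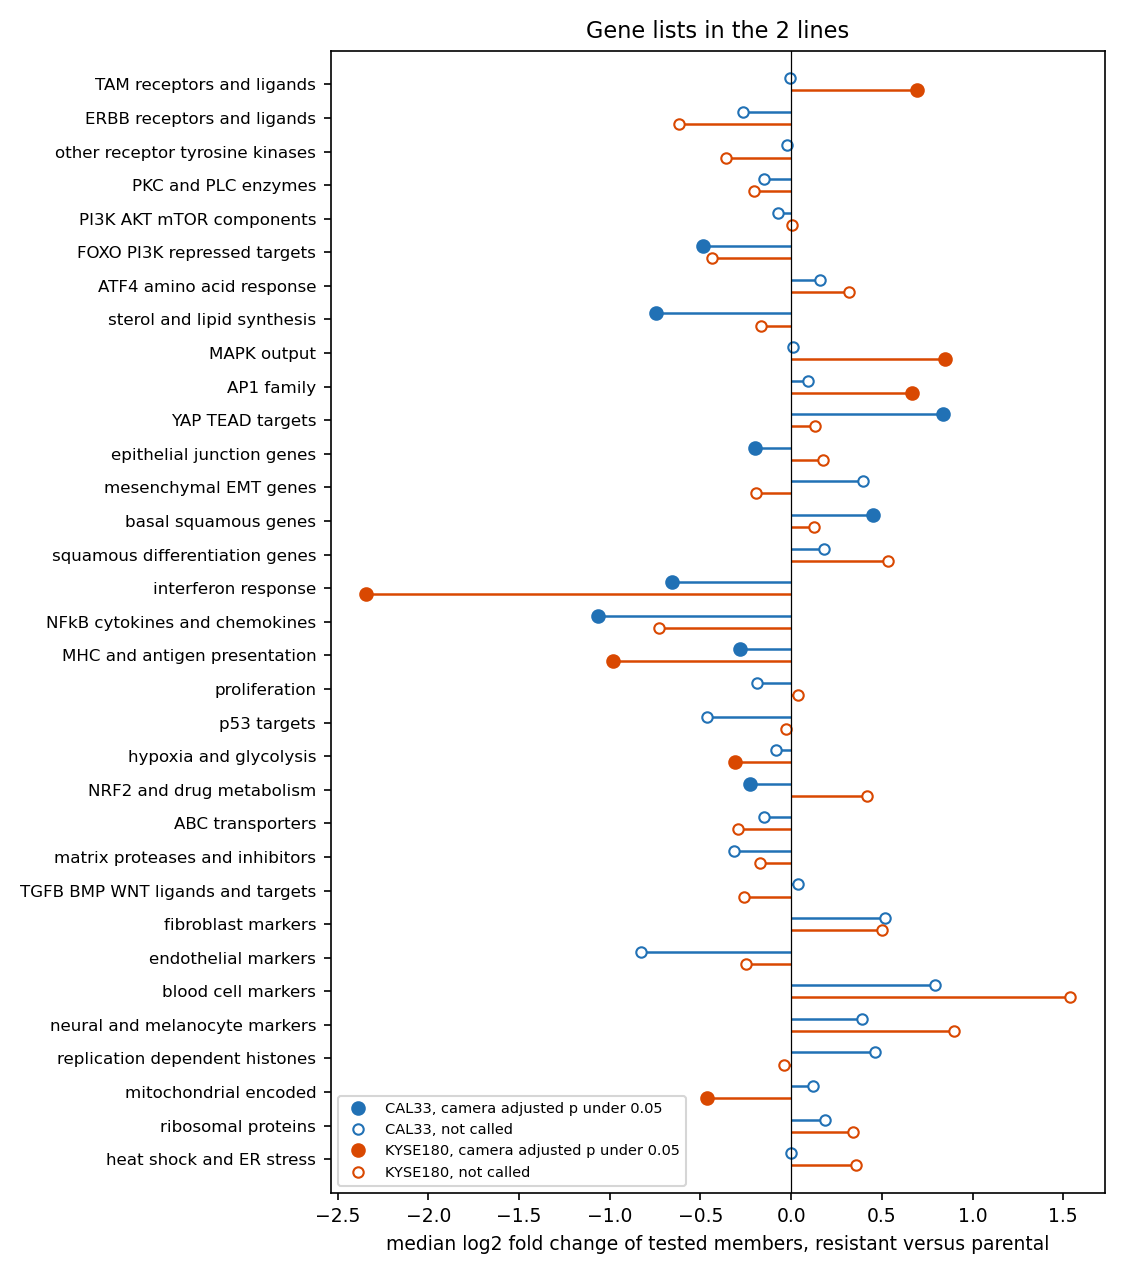
Median log2 fold change (resistant versus parental) of the tested members of each of the 33 gene lists in CAL33 (blue) and KYSE180 (orange), with filled points for a camera adjusted p under 0.05 at the preset correlation. Interferon-response genes had the lowest median, -2.34 in KYSE180, and 0 of the 16 filled points passed with an estimated correlation.

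Changes shared by both lines went beyond AXL. Keratin 14, the neural cell adhesion molecule L1CAM and the semaphorin SEMA7A rose in both, and the chemokines CCL2 and CXCL1 fell. KRT14 rose from 594 to 4761 CPM in KYSE180 (3.003 ± 0.20). L1CAM rose by 2.28 ± 0.24 in CAL33 and 2.90 ± 0.22 in KYSE180, SEMA7A by 1.75 ± 0.26 and 2.76 ± 0.33, and SH2D5 by 1.70 ± 0.19 and 2.59 ± 0.22. The noncoding LINC00707 rose by 2.46 ± 0.24 and 3.001 ± 0.26. The keratin pseudogenes KRT16P6 (2.95 ± 0.29 and 3.21 ± 0.32) and KRT16P4 (1.84 ± 0.31 and 3.54 ± 0.35) also rose, but their sequence is close to that of keratin 16 and their counts are uncertain. Shared falls included CCL2 (-3.81 ± 0.36 in KYSE180), CXCL1 (-2.29 ± 0.19 in KYSE180), XAF1 (-2.44 ± 0.18 in CAL33) and NOS1 (-2.18 ± 0.21 in CAL33). The stress-induced regulator NUPR1 (-3.07 ± 0.23 and -2.77 ± 0.30), AMOT, a regulator of YAP (-4.49 ± 0.21 and -2.63 ± 0.20), and GGT6 (-3.12 ± 0.29 and -2.51 ± 0.31) also fell in both. The largest adjusted p among these 15 genes, AXL included, in either line was 0.000955.

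Of 1205 genes called in both lines, 921 (76.4%) changed in the same direction. Both lines had 349 higher genes in common where independent lists would share 138.3 (ratio 2.52, one-sided Fisher's exact p = 1.16e-66). They shared 572 lower genes where 202.2 were expected (ratio 2.83, exact p = 2.45e-138). Genes higher in CAL33 and lower in KYSE180 numbered 127 (134.5 expected, exact p = 0.774), and the reverse numbered 157 (208 expected, ratio 0.755, exact p = 1). The one-sided test looks only for an excess, so it does not assess the deficit in the latter. These p-values treat genes as independent, which they are not, and the comparisons share no library. Over all 20154 tested genes the log2 fold changes of the 2 lines had a Pearson correlation of 0.167 and a Spearman correlation of 0.177, across genes and not across replicates. With the GC and length trend removed, a setting chosen after the data were seen, 1748 genes shared a direction (829 higher and 919 lower). The number of same-direction genes was 556 without CAL33 parental replicate 2, 571 without CAL33 resistant replicate 2, 545 without KYSE180 parental replicate 1 and 561 without KYSE180 parental replicate 2.

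**Figure D4:**
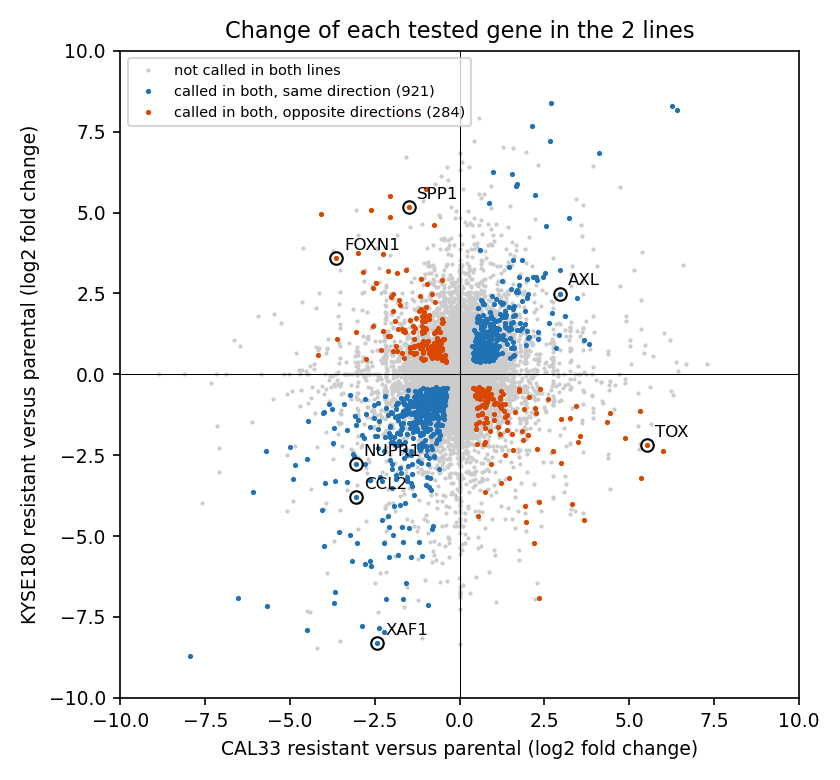
Log2 fold change (resistant versus parental) of each of the 20154 tested genes in CAL33 (horizontal axis) and KYSE180 (vertical axis), with genes called in both lines in blue (same direction) or orange (opposite directions) and circles around labelled genes. The same direction was taken by 921 of the 1205 genes called in both.

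The change differed between the lines for 2691 genes by the interaction term of the same edgeR model. TOX rose in CAL33 and fell in KYSE180 from 12.6 to 2.73 CPM (-2.20 ± 0.25), and EPHA3 rose in CAL33 and went to 2 counts in KYSE180, lower by a ratio of 25.2, counting interval 6.7 to 212. SULF1 fell in KYSE180 from 107 to 11.6 CPM (-3.21 ± 0.25). In CAL33 it was called higher, with 0 counts in parental libraries and 14 over the resistant ones, 3.77 times the parental floor. That call for SULF1 was lost with adjusted p of 0.115 without CAL33 parental replicate 1, 0.091 without CAL33 parental replicate 2 and 0.0892 without CAL33 resistant replicate 3. SLCO2A1 fell in KYSE180 (-2.36 ± 0.36) and had 1 count in CAL33 parental libraries, with a ratio of 80.8, counting interval 14.2 to 3220 in resistant ones. SLITRK5 fell in KYSE180 (-4.31 ± 0.42) and was at or under the floor of 3 counts in both CAL33 groups. FOXN1, a regulator of keratinocyte differentiation, rose in KYSE180 from 0.8 to 9.7 CPM (3.59 ± 0.43) and fell in CAL33 (-3.65 ± 0.56). LINC01010 rose in KYSE180, and in CAL33 it changed by -0.99 ± 0.31 (adjusted p = 0.0472, and 0.199 without CAL33 parental replicate 1, 0.0824 without CAL33 parental replicate 2, 0.117 without CAL33 resistant replicate 1, 0.0635 without CAL33 resistant replicate 2, 0.148 without CAL33 resistant replicate 3, 0.0594 without KYSE180 resistant replicate 1 and 0.0615 without KYSE180 resistant replicate 2). SERPINB4 and ADAM28 were at 0 in KYSE180 parental libraries. They had 7 and 6 counts over the resistant ones, 3.06 and 2.62 times the parental floor. In CAL33 ADAM28 fell (-2.05 ± 0.32). In KYSE180 the call for SERPINB4 was lost with adjusted p of 0.0846 without KYSE180 parental replicate 1, 0.0665 without KYSE180 parental replicate 2 and 0.0879 without KYSE180 resistant replicate 1, and that for ADAM28 with 0.106 without KYSE180 parental replicate 1, 0.0857 without KYSE180 parental replicate 2 and 0.0766 without KYSE180 resistant replicate 1. CNNM1 had 44 counts over the CAL33 parental libraries, 18.2 times the resistant floor, and 0 in resistant ones. Its value in KYSE180 was -0.25 ± 0.31 (adjusted p = 0.594). These 10 genes, named for the 5 largest differences in each direction, had adjusted p of the difference of at most 0.00926. Of the 2691 genes, 1217 changed more towards higher levels in CAL33 and 1474 more towards higher levels in KYSE180. That balance depended on the scaling and the test, at 1332 and 1332 with DESeq2 size factors, 1470 and 1361 with upper-quartile factors, 1788 and 1596 with no filter and 1529 and 1483 with the DESeq2 Wald test. The count was 1787 without CAL33 resistant replicate 2, 1467 without KYSE180 parental replicate 1 and 1634 without KYSE180 parental replicate 2, and 4723 with the GC and length trend removed, a setting chosen after the data were seen.

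By the same camera test applied to the difference, 8 of 33 lists changed differently in the 2 lines, and 0 did with an estimated correlation (3 had an unadjusted p under 0.05, and fry called 15). Members with a called difference are counted first towards higher and then towards lower levels in CAL33 relative to KYSE180. Interferon-response genes had 17 and 1 of 25 members with a called difference (19 and 2 adjusted over the list alone) and a median difference of 1.80. Camera for interferon-response genes gave adjusted p = 1.53e-09, and adjusted p = 0.458 with an estimated correlation. Hypoxia and glycolysis genes had 4 and 1 of 22 members with a called difference (8 and 1 adjusted over the list alone) and a median difference of 0.45. Camera for hypoxia and glycolysis genes gave adjusted p = 0.018, and adjusted p = 0.523 with an estimated correlation. The difference in the hypoxia list lost its call with adjusted p of 0.0601 without KYSE180 resistant replicate 1. Mitochondrially encoded genes had 3 and 0 of 13 members with a called difference (4 and 0 adjusted over the list alone) and a median difference of 0.55. Camera for mitochondrially encoded genes gave adjusted p = 0.00944, and adjusted p = 0.665 with an estimated correlation. The difference in the mitochondrial list lost its call with adjusted p of 0.091 without KYSE180 resistant replicate 2. Sterol and lipid synthesis genes had 0 and 8 of 19 members with a called difference (0 and 14 adjusted over the list alone) and a median difference of -0.69. Camera for sterol and lipid synthesis genes gave adjusted p = 5.94e-05, and adjusted p = 0.458 with an estimated correlation. Sterol genes with a called difference numbered 4 without KYSE180 parental replicate 1 and 14 with the GC and length trend removed. MAPK output genes had 2 and 9 of 16 members with a called difference (3 and 10 adjusted over the list alone) and a median difference of -0.73. Camera for MAPK output genes gave adjusted p = 0.00944, and adjusted p = 0.458 with an estimated correlation. NRF2 targets and drug-metabolism genes had 2 and 10 of 23 members with a called difference (3 and 10 adjusted over the list alone) and a median difference of -0.26. Camera for NRF2 targets and drug-metabolism genes gave adjusted p = 0.0154, and adjusted p = 0.458 with an estimated correlation. Epithelial junction genes had 2 and 9 of 21 members with a called difference (3 and 12 adjusted over the list alone) and a median difference of -0.58. Camera for epithelial junction genes gave adjusted p = 0.0233, and adjusted p = 0.512 with an estimated correlation. The difference in the epithelial list lost its call with adjusted p of 0.0571 without CAL33 resistant replicate 3 and 0.0946 without KYSE180 resistant replicate 2. That difference was also lost with the GC and length trend removed (adjusted p = 0.0768). AP-1 family genes had 0 and 2 of 11 members with a called difference (0 and 6 adjusted over the list alone) and a median difference of -0.66. Camera for AP-1 family genes gave adjusted p = 0.0441, and adjusted p = 0.511 with an estimated correlation. The difference in the AP-1 list lost its call with adjusted p of 0.125 without CAL33 parental replicate 1, 0.0639 without CAL33 parental replicate 2, 0.0639 without CAL33 resistant replicate 1, 0.0831 without CAL33 resistant replicate 3, 0.0971 without KYSE180 parental replicate 1, 0.192 without KYSE180 parental replicate 2, 0.0966 without KYSE180 resistant replicate 1 and 0.0963 without KYSE180 resistant replicate 2. That difference was also lost with the GC and length trend removed (adjusted p = 0.114).

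Among markers of other cell types, 6 of 10 fibroblast, 5 of 9 endothelial, 6 of 10 blood cell and 7 of 9 neural or melanocyte markers were under 1 CPM in every library. The highest of each list in a single library were, in the order of their levels, CDH5 (49.8 CPM), COL1A1 (34.8 CPM), CD14 (15.7 CPM) and TUBB3 (4.32 CPM). None of these lists passed the camera test in either line. Fibroblast markers in CAL33 had 1 higher and 0 lower of 4 (1 and 0 adjusted over the list alone, camera adjusted p = 0.299). Endothelial markers in CAL33 had 1 higher and 1 lower of 4 (1 and 2 adjusted over the list alone, camera adjusted p = 0.817). Blood cell markers in CAL33 had 0 higher and 1 lower of 5 (1 and 1 adjusted over the list alone, camera adjusted p = 0.817). Neural and melanocyte markers in CAL33 had 1 higher and 0 lower of 2 (1 and 1 adjusted over the list alone, camera adjusted p = 0.595). LUM was the fibroblast marker that rose. Fibroblast markers in KYSE180 had 0 higher and 1 lower of 4 (0 and 1 adjusted over the list alone, camera adjusted p = 0.624). Endothelial markers in KYSE180 had 1 higher and 2 lower of 4 (1 and 2 adjusted over the list alone, camera adjusted p = 0.786). Blood cell markers in KYSE180 had 2 higher and 0 lower of 5 (2 and 0 adjusted over the list alone, camera adjusted p = 0.133). Neural and melanocyte markers in KYSE180 had 1 higher and 0 lower of 2 (1 and 0 adjusted over the list alone, camera adjusted p = 0.299). Blood cell markers passed without KYSE180 parental replicate 1 (adjusted p = 0.00131) and without KYSE180 resistant replicate 2 (adjusted p = 0.0486). The median of 0.50 of the fibroblast list in KYSE180 includes the fitted value of LUM. LUM had 0 counts in KYSE180 parental and 2 in resistant libraries, so it has no fold there.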

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

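The tests of technical explanations in this part were chosen only after the result was seen, except that for RNA of the other line, while the test of the difference between the 2 lines was planned.

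Changes that differed between the 2 lines by the interaction term of the edgeR model were found for 79 of the 121 genes named. Most of these genes were named for large changes in these same data, and some for the largest differences. Their count is therefore raised by the selection, and over all 20154 tested genes 2691 (13.4%) differed. The values given are the CAL33 log2 fold change minus that in KYSE180. Changes lay further towards higher levels in CAL33 for SULF1 (8.56), SLCO2A1 (8.36), EPHA3 (8.18), TOX (7.71), SLITRK5 (7.57), MSLN (7.06), PRRX1 (6.96), KIT (6.86), XAF1 (5.88), FGF13 (5.81), CDH2 (5.64), CIDEB (5.37), ANKRD1 (5.15), NOS1 (4.76), BMP4 (4.37), TENM2 (4.2), IFI44L (3.99), KRT4 (3.95), BST2 (3.88), OAS2 (3.76), EHF (3.5), ADAMTS1 (3.5), EPHA4 (3.46), CA9 (3.27), CPA6 (3.08), FBXO32 (2.72), NPR3 (2.6), BTC (2.07), MMP10 (1.99), PIK3R3 (1.86), PSMB9 (1.85), FAS (1.57), PSMB8 (1.56), HLA-B (1.38), MT-ND6 (1.26), MT-ND4L (1.23), EGFR (1.18), CLDN1 (1.16) and KRT8 (0.96). They lay further towards higher levels in KYSE180 for TYRO3 (-0.7), KRT14 (-0.83), SH2D5 (-0.89), PSAT1 (-1.08), FOSL1 (-1.11), FASN (-1.17), TGFB2 (-1.45), OSGIN1 (-1.52), IFI27 (-1.57), GRHL1 (-1.58), KRT16P4 (-1.7), AMOT (-1.86), FOS (-1.96), PLCB1 (-1.99), SDF2L1 (-2.52), SPRY4 (-2.74), CYP4X1 (-2.75), ETV4 (-2.8), TJP3 (-2.81), GDF15 (-2.86), ETV5 (-3.19), AKR1C3 (-3.23), AKR1B10 (-3.24), SCD (-3.4), ANXA10 (-3.52), CD74 (-3.69), ABCA1 (-4.04), ALDH1A1 (-4.37), TMPRSS11D (-4.47), DLC1 (-4.57), PLXDC2 (-4.64), CP (-4.79), TGM2 (-4.83), SMOC2 (-5.54), SPP1 (-6.66), LINC01010 (-6.73), ADAM28 (-6.91), CNNM1 (-7.06), FOXN1 (-7.24) and SERPINB4 (-7.68). Fitted differences of genes with no count in 1 group (SULF1, SLITRK5, PRRX1, DLC1, ADAM28, CNNM1 and SERPINB4) depend on the prior count, and so do those with 1 to 3 counts in a group (SLCO2A1, EPHA3, MSLN, XAF1 and SMOC2). In libraries left out in turn, numbered by replicate, the adjusted p of the difference passed 0.05 for CPA6 (0.118 without CAL33 resistant 1), CYP4X1 (0.0864 without KYSE180 resistant 1, 0.056 without KYSE180 resistant 2), DLC1 (0.0527 to 0.152 without each of 6 libraries: CAL33 parental 1, CAL33 resistant 1, CAL33 resistant 2, CAL33 resistant 3, KYSE180 parental 1, KYSE180 parental 2), FASN (0.0578 without KYSE180 parental 1), KRT14 (0.0691 to 0.131 without each of 7 libraries: CAL33 parental 1, CAL33 resistant 1, CAL33 resistant 2, CAL33 resistant 3, KYSE180 parental 1, KYSE180 parental 2, KYSE180 resistant 2), KRT16P4 (0.183 without CAL33 parental 1, 0.0896 without KYSE180 parental 1, 0.107 without KYSE180 resistant 2), KRT8 (0.0529 without KYSE180 parental 2), MT-ND6 (0.0528 without KYSE180 parental 1), PRRX1 (0.0757 without CAL33 parental 1, 0.222 without CAL33 resistant 1, 0.0653 without KYSE180 parental 2), SH2D5 (0.0642 to 0.208 without each of 8 libraries: CAL33 parental 1, CAL33 parental 2, CAL33 resistant 1, CAL33 resistant 2, CAL33 resistant 3, KYSE180 parental 1, KYSE180 parental 2, KYSE180 resistant 2) and TYRO3 (0.0673 to 0.144 without each of 8 libraries: CAL33 parental 1, CAL33 parental 2, CAL33 resistant 1, CAL33 resistant 2, CAL33 resistant 3, KYSE180 parental 1, KYSE180 parental 2, KYSE180 resistant 2). The difference for CP was 0.056 (adjusted p = 0.911) without KYSE180 resistant 1, which leaves KYSE180 resistant 2 with no CP count. Of the 33 gene lists, 8 differed between the lines, with median differences of 1.80 for interferon response, 0.55 for mitochondrially encoded genes, 0.45 for hypoxia and glycolysis, -0.26 for NRF2 targets and drug metabolism, -0.58 for epithelial junction genes, -0.66 for the AP-1 family, -0.69 for sterol and lipid synthesis and -0.73 for MAPK output, while 0 of the 33 passed with an estimated correlation. The share of reads that were not aligned was 16.9% in KYSE180 resistant 2, above the highest share in a parental library (10.9%). Those reads are not analysed here.

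More genes moved the same way in both resistant derivatives than independent lists would share, by ratios of 2.52 for higher and 2.83 for lower genes. With the GC content and length trend removed per library the lower of the 2 ratios was 2.13, which argues against that trend as the whole cause. RNA of the other line reached at most 0.139% of its parental level in a resistant library, which argues against mixing of the lines as the cause. Genes called in opposite directions had ratios of at most 0.944. Well-measured genes passing in both lines whatever their direction are therefore not the whole cause of the excess. A part from that source is not excluded, because shared directions lower the opposite counts. An earlier test, fitting each line alone so that no spread was shared, gave a lower ratio of 2.10. Acquired resistance is a candidate explanation that these libraries leave open, beside drug exposure at harvest, which the labels do not assign, and passage in culture, none of which was tested.

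Interferon-response genes fell further in KYSE180 than in CAL33, with a median difference of 1.80. The lowest median difference with any 1 library left out was 1.203 (without KYSE180 parental 1), and 1.60 without KYSE180 resistant 2, the library first singled out for this test, so no single library accounts for it. With the GC content and length trend removed the median difference was 1.81. With an estimated correlation the list did not pass (adjusted p = 0.458). The difference may lie between the 2 derivatives themselves, and the drug exposure of each library, the media of the 2 lines, which differed, and the history of each culture stay open and untested.

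Sterol and lipid synthesis genes fell further in CAL33 than in KYSE180, with a median difference of -0.69, a pattern picked for weighing after its value was known. Leaving out any 1 library brought the median difference no nearer to 0 than -0.54 (without CAL33 parental 2), while the 8 members with a called difference became 4 without KYSE180 parental 1. With the GC content and length trend removed it was -0.70, with 14 such members. With an estimated correlation the list did not pass (adjusted p = 0.458). A difference between the derivatives may underlie it, and the media of the 2 lines and the unassigned drug exposure stay open and untested.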

How the results depend on the processing

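The removal of the GC content and length trend was chosen only after the data were seen, and all other alternatives were planned before the data were examined.

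AXL kept its direction and passed the test in every alternative run, at 2.88 to 3.04 in CAL33 and 2.40 to 2.58 in KYSE180. With other scaling factors, other filters, DESeq2, limma-voom or each line fitted alone, no total of called genes moved by over 1.5 times, while the genes higher in CAL33 (1082, 39.9%) were 1665 (48.7%) with each line fitted alone. The counts in CAL33 (2709), in KYSE180 (5081), of differing genes (2691) and of same-direction genes (921) moved with the threshold, to 1454, 2789, 1262 and 410 at an adjusted p under 0.01 and, for CAL33, KYSE180 and same-direction genes, to 1130, 2317 and 313 at 2-fold or more. With the GC content and length trend removed, 4666 genes were called in CAL33, 4723 differed and 1748 shared a direction, and the cause was not tested. The SD of the removed log2 trend over genes was largest in KYSE180 resistant replicate 2 (0.335) and CAL33 parental replicate 2 (0.27). In the other libraries it was 0.0328 to 0.144. The replicate pairs that hold these libraries also had the highest chi-square per degree of freedom, 46.37 and 44.61, against 11.97 to 25.99 in other pairs. Leaving out each library in turn gave 1534 to 3714, 2677 to 5577, 1467 to 3412 and 545 to 1219, where fewer libraries remain and a lone library is assumed to vary like the other groups. Pairing by number was not established. Correlations of deviations in CAL33 were -0.724 and -0.152 for libraries of the same title number and -0.724 and -0.618 for the same description number. Deviations of the 2 CAL33 parental libraries mirror each other. The 0.152 to 0.724 of other pairs are therefore the same values with the sign turned, and not a separate contrast. The 0.104 of same-numbered KYSE180 libraries rests on 2 per group and leaves pairing there open. With the title number as a replicate block the counts were 1328 in CAL33, 1412 of differing and 443 of same-direction genes. With the description number as the block the counts were 1161 in CAL33, 3312 in KYSE180, 1245 of differing and 378 of same-direction genes. With either block 1 CAL33 resistant library has no parental partner and adds nothing to the CAL33 contrast. The lower counts that involve CAL33 therefore mix the loss of that library with any effect of pairing.

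Of 66 list results, 16 were called, 0 with an estimated correlation (6 at an unadjusted p under 0.05), 33 by fry, which compares a list with no change and not with other genes, and 10 to 17 with a library left out, 10 being without KYSE180 resistant replicate 1. With the trend removed, the FOXO (adjusted p = 0.0847) and NRF2 (0.0932) lists in CAL33 and the AP-1 list in KYSE180 (0.102) no longer passed. With the title block 11 lists were called, without FOXO (0.114), epithelial (0.172) and NRF2 (0.0796) in CAL33 and AXL family (0.0796) and hypoxia (0.0523) in KYSE180. The difference in the epithelial list was lost with the trend removed (0.0768) and the title block (0.0929), and so was that in the AP-1 list (0.114 and 0.103). With CPM of at least 1 in 2 libraries the FOXO (0.0526) and epithelial (0.0529) lists in CAL33 and the AXL family list in KYSE180 (0.0529) did not pass and blood cell markers in KYSE180 did (0.0139). The AXL family list also missed the threshold with DESeq2 size factors (0.0502), and the mitochondrial list with fry (0.115, and 0.153 for its difference).

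Directions turned in these instances, none of which passed the test on the other side, and the cause was not tested. With a library left out, EGFR in CAL33 was at -0.15 to 0.026, PIK3CA in KYSE180 at -0.57 to 0.011 (0.043 with the trend removed) and the CP difference at -5.49 to 0.056. For lists, what turned was the direction of the test, and the values given are medians. In CAL33 the medians with a library left out were -0.29 to -0.16 for ERBB ligands (-0.27 with fry, -0.19 with the title block), -0.27 to 0.072 for PKC and PLC enzymes (0.069 with the title block), -0.10 to -0.0040 for PI3K components, -0.049 to 0.22 for the ATF4 response (0.16 with fry), -1.34 to -0.15 for endothelial markers (-0.82 with fry) and -0.29 to 0.95 for blood cell markers (0.73 with the title block), and matrix proteases were at -0.31 with fry. In KYSE180 they were -0.046 to 0.016 for PI3K components (0.047 with the trend removed), 0.011 to 0.089 for proliferation, -0.18 to 0.13 for p53 targets (-0.058 with DESeq2 size factors, -0.028 with fry) and -1.52 to 0 for endothelial markers, and histones were at -0.50 with the trend removed.

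Among 266 results of single genes over all alternatives, 5269 values kept direction and side of the threshold, 227 lost the threshold, 2 gained it and 4 turned. Most of these genes were named for large changes, so this does not describe called genes at large. Of all 2709 CAL33 calls, 1628 were kept without CAL33 resistant replicate 2, 1309 with the title block and 1147 with the description block. Of all 5081 KYSE180 calls, 3659 were kept with the title number as a block and 3298 with the description number. Still fewer KYSE180 calls were kept without either parental library, which leaves a lone library in that group. Leaving out a library ended 42 calls of 33 genes. In simulated counts, 26.9% (CAL33) and 25.4% (KYSE180) of 1.5-fold changes were recovered. Those simulations gave 136 and 141 calls, against 2709 and 5081 in the data. With fewer calls the adjusted threshold is stricter, so these shares do not measure what these libraries can show.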

Other observations

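The comparison of call numbers in this part was made only after the result was seen.

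The KYSE180 comparison called 1.88 times as many genes as the CAL33 comparison, and that ratio depended on single libraries. It was 0.985 without KYSE180 resistant replicate 2 (3658 genes in KYSE180 and 3714 in CAL33), 1.59 without KYSE180 resistant replicate 1, 1.15 and 1.21 without KYSE180 parental replicates 1 and 2, and 2.22 to 3.58 without each CAL33 library. It was 1.47 with the GC content and length trend removed and 1.40 with each line fitted alone. The first test made of it looked at this ratio of calls alone, and its value without KYSE180 resistant replicate 2 met what that library alone would give. Without that library the calls in CAL33 also went from 2709 to 3714. The median absolute log2 fold change over 11931 genes at 5 CPM or more was 0.24 in CAL33 and 0.35 in KYSE180, a ratio of 1.47. That ratio was 1.34 without KYSE180 resistant replicate 2 (0.24 and 0.32), 1.81 without KYSE180 resistant replicate 1, 1.16 without CAL33 parental replicate 1 and 1.39 to 1.51 without each of the other libraries. Such a median lies above 0 with no change at all and grows with noise and with fewer libraries, and its value under no change was not computed, so it does not show which line changed more.

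Markers of endothelial and blood cells that fell in CAL33 were CDH5 (-1.55 ± 0.23, adjusted p = 0.000313) and CD14 (-1.97 ± 0.22, adjusted p = 2.22e-05), by the edgeR test. On the same lists ERG rose in CAL33 from 0.344 to 4.14 CPM (3.56 ± 0.45, adjusted p = 6.23e-05) and fell in KYSE180 (-1.90 ± 0.48, adjusted p = 0.0095), and CSF1R was at 1.04 and 2.93 CPM in the CAL33 groups (1.502 ± 0.54, adjusted p = 0.0833). Mean CDH5 was 43.5 CPM in CAL33 parental and 14.8 CPM in CAL33 resistant libraries and at most 0.0658 CPM in a KYSE180 group, and CD14 was at 14.2 and 3.63 CPM in the 2 CAL33 groups. CD14 rose in KYSE180 at a low level, from 0.164 to 0.664 CPM (1.97 ± 0.43, adjusted p = 0.00356), and the difference between the lines passed the test (adjusted p = 5.97e-05). These 4 genes were singled out after their values were seen.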
